A study of Mus musculus with 12 samples.

How the data were processed

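RNA was sequenced from HL-1 cells, a mouse line derived from atrial heart muscle cells and labelled as a cardiac muscle cell line, grown in DMEM with fetal bovine serum. The labels name 3 groups of 4 libraries each. Control cells (CON) received viruses carrying the lentiCRISPRv2 and pCDH vectors. Knockdown cells (KD) received virus carrying a CRISPR guide against Wdr62. Re-expression cells (RE) were KD cells that also received a pCDH virus for flag-tagged wild-type WDR62. The labels state the pCDH vector for CON and RE and not for KD, so any response to that vector falls on the same side of KD in both groups. Total RNA was extracted with TRIzol and made into Illumina libraries, per the labels' protocols.

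The values used are TPM (transcripts per 1000000 transcripts), which the authors deposited as 1 table of 23184 gene symbols by 12 libraries. Reads were trimmed with Trim Galore 0.6.6 and processed with TopHat2 2.1.1 and Cufflinks 2.2.1 on the mm10 genome build, per the submitters' processing notes; how these tools led to TPM, and whether strand was used, is not given in the sources used here. Each TPM column of the deposited table sums to 1000000, so the table holds no sequencing depth. The depth is therefore unknown, and no counting interval or detection limit is given. Of the symbols, 6088 are listed at 0 in every library. Mitochondrially encoded genes were not analysed here. Genes with many near-identical copies can be understated in such a table: Rpl3, a ribosomal protein gene used by every cell, had 17.8 TPM in CON, and Rps29 2.50 TPM. A value of 0 can therefore be a failed estimate and is reported only as listed at 0. The 4 control columns carry the name WT; they were taken as the 4 CON libraries because the labels give CON the WT genotype, and their numbers pair them with no other library. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

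Genes with a mean TPM of at least 1 over the 12 libraries were tested, 11774 in all. Values were put on the log2(TPM + 1) scale, on which a fold change understates the change of low genes. All 12 libraries entered 1 linear model with a mean per group in limma 3.58.1 (R 4.3.3; moderated test with a mean-variance trend, two-sided), and p-values were adjusted over the tested genes with the Benjamini-Hochberg method for each comparison. Genes with an adjusted p below 0.05 count as changed, and every adjusted p for a gene below comes from this limma test. Wdr62 was also tested with an exact two-sided permutation test of 4 against 4 log2 values, whose smallest possible p is 0.0286. Genes that changed in KD against CON and changed the opposite way in RE against KD are called reversed. This count and the overlap of KD and RE changes use shared libraries, so each is given beside 100 simulations of unchanged groups with the same shared libraries, beside the overlap of independent lists and beside the 6 ways of giving each comparison 2 of the 4 shared libraries.

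The 36 gene lists, the rule for named genes, the tests and the first set of alternatives were chosen before the data were examined. The 31 lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists for each comparison. Camera was repeated with an estimated correlation, and fry was run beside it; fry's directional test asks whether the members move, on balance, 1 way, its mixed test whether they change in either direction, and neither compares the list with other genes. Members that changed are counted over all genes tested and adjusted over the list alone. Named genes have a symbol that occurs once, are not predicted or clone names, and have a mean of at least 5 TPM: Wdr62, the 8 largest rises and 8 largest falls of KD against CON and of RE against KD (4 and 4 for RE against CON) among changed genes whose groups do not overlap, and the 6 largest reversed genes in each direction. Up to 4 changed members of each list, with a mean of at least 1 TPM, were added; other names are given for their values. Of the genes this rule names, 1 is not reported here.

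Alternatives were a pseudocount of 0.1, no TPM filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, the replicate number as a block, the 2 compared groups alone, robust variance moderation, an additional log2 fold change of at least 1, and leaving out each library. The groups share 1 estimate of the spread. Leaving out a library of the group outside a comparison therefore changes the p-values of that comparison and not its fold changes. After the data were seen, 4 others were added: subtraction of a smooth trend on transcript length from each library (loess, span 0.5), limma array weights, leaving out CON 4, RE 1 and RE 3, and leaving out CON 4 with the length correction. The block with the length correction and the list tests without each library were added at the same time. Transcript lengths, GC content and positions come from GENCODE release M21 (genome build GRCm38, of which mm10 is the browser's name), which gave a length for 11704 tested genes (99.4%), 365 of them through an older symbol; the median length was 2090.5 bases. Chromosome medians were compared with 10000 random draws of genes.

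The model was tested on simulated data for KD against CON over 11774 genes, with each gene's mean over the 12 libraries and its spread in the model. It found 2.70% of genes changed by 0.5 on the log2 scale, 37.9% of those changed by 1 and 89.4% of those changed by 2, and 4.20% of its calls were false over 5 simulations. Of unchanged simulated lists, 2.80% had a camera p below 0.05. Simulated genes varied independently of each other and no simulated library stood apart. These rates therefore do not cover lists of correlated genes or a library such as CON 4. Tables were prepared with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.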

Results

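The series measured gene expression in HL-1 cells by RNA sequencing to find the genes most related to the expression of Wdr62, a WD40-repeat protein of the centrosome and mitotic spindle whose human counterpart is mutated in primary microcephaly. The 12 libraries formed 3 groups of 4: vector control cells (CON), cells given a CRISPR guide against Wdr62 (KD), and KD cells given a WDR62 expression virus (RE). Between 14060 and 14733 genes were above 0 TPM in a library, and the 50 most abundant genes took 18.6% to 30.3% of the TPM. The smallest Spearman correlation between any pair of libraries was 0.939. No pair held identical values. CON 1 and CON 2 were the closest, with a median absolute log2 difference of 0.11. CON 4, RE 1 and RE 3 stood apart from the other libraries of their groups in their long transcripts. In the 2341 genes with the longest transcripts (at least 3712 bases), the median deviation from the gene mean was -0.77 in CON 4 against 0.44 to 0.65 in the other 3 CON libraries, -0.66 in RE 1 and -0.96 in RE 3 against -0.08 and -0.10 in RE 2 and RE 4. All values below are mean ± SD of TPM with n = 4 libraries per group unless a library is named, and fold changes are on the log2(TPM + 1) scale with their standard error (SE).

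Wdr62 lies on chromosome 7 between 30240138 and 30280419 of GRCm38, on the minus strand (ENSMUSG00000037020.16). Its level was 7.46, 6.61, 6.50 and 3.38 TPM in the CON libraries, 1.40, 0.944, 1.37 and 0.881 TPM in the KD libraries, and 1.47, 0.772, 0.827 and 1.99 TPM in the RE libraries. Wdr62 was lower in KD than in CON by a log2 fold change of -1.67 ± 0.25 (SE, adjusted p = 0.000921, exact permutation p = 0.0286), and every KD library lay below every CON library. In RE, Wdr62 stood at 1.26 ± 0.58 TPM against 1.15 ± 0.28 in KD and 5.99 ± 1.79 in CON. The difference between RE and KD was 0.05 with a 95% interval of -0.48 to 0.58 (adjusted p = 0.895, exact permutation p = 0.886). RE remained below CON by -1.62 ± 0.25 (adjusted p = 0.00147, exact permutation p = 0.0286). The labels do not say from which species or with which codons the WDR62 construct was made, so the mouse Wdr62 value may leave the construct's transcripts uncounted and is no measure of the protein.

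**Figure D1:**
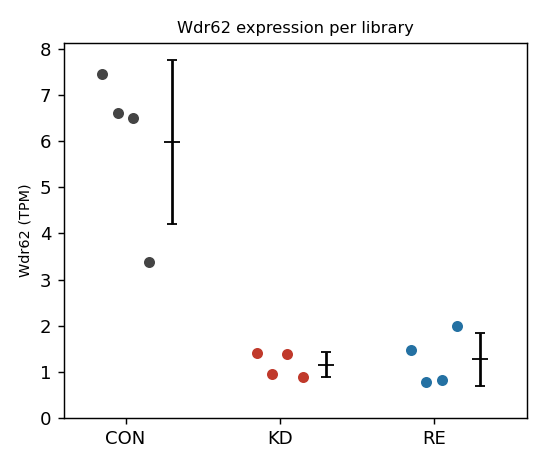
Wdr62 in TPM in each of the 12 libraries, 1 point per library, with the group mean and SD as black bars. The 4 KD libraries lie between 0.881 and 1.40 TPM and the 4 RE libraries between 0.772 and 1.99 TPM, all below the lowest CON library at 3.38 TPM.

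KD was compared with CON to find which genes changed when Wdr62 was targeted. Lcn2, Camp and Hp, which encode secreted proteins, rose in KD, and Igfbp5, Igfbp2, Aldh3a1 and the prolactin-family genes Prl2c2 and Prl2c3 fell. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose from 155 ± 206 to 1849 ± 407 TPM, a log2 fold change of 4.35 ± 0.73; CON 4 stood at 464 TPM against 40.2 to 72.5 in the other CON libraries, and without CON 4 the log2 fold change was 5.14. Igfbp5, a binding protein of insulin-like growth factors, fell from 488 ± 221 to 0.882 ± 0.392 TPM, a log2 fold change of -7.86 ± 0.44. Aldh3a1, an aldehyde dehydrogenase, fell from 296 ± 22.7 to 7.17 ± 1.69 TPM (-5.20 ± 0.19). In total 1202 of 11774 genes changed, 777 higher and 425 lower, and 693 of them (450 higher, 243 lower) changed by at least 1 on the log2 scale.

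The other large rises in KD were Xlr3a (3.91), Ptn for the heparin-binding growth factor pleiotrophin (3.85), Slc6a12 for a betaine and GABA transporter (3.76), Camp for the antimicrobial peptide cathelicidin (3.65), H2-DMb2 of the class II antigen presentation machinery, Hp for the haemoglobin-binding protein haptoglobin (3.52) and Pex5l (3.44). Ptn went from 38.7 ± 15.1 to 533 ± 85.1 TPM, Camp from 16.3 ± 9.66 to 199 ± 52.5 TPM, and Hp from 133 ± 94.4 to 1331 ± 191 TPM. H2-DMb2 was listed at 0 in CON 2 and at 0.115 to 0.364 TPM in the other CON libraries, against 10.8 to 16.1 TPM in KD. Other large falls were the prolactin-family genes Prl2c2 (-5.25) and Prl2c3 (-5.25), the cytochrome P450 gene Cyp4f40 (-4.72), Igfbp2 for a further insulin-like growth factor binding protein (-4.33) and P2rx3 for an ATP-gated ion channel (-4.33). Prl2c2 fell from 599 ± 106 to 15.9 ± 6.61 TPM. Igfbp2 was listed at 0 in KD 1, KD 2 and KD 3 and at 0.189 TPM in KD 4, against 10.6 to 81.3 TPM in CON. The adjusted p of these genes lay between 1.23e-08 for Aldh3a1 and 0.00235 for Lcn2, and all of them stayed changed under every alternative run for single genes. Prl2c2 and Prl2c3, H2-DMb2 and H2-DMb1, and Xlr3a have near-identical relatives among which reads may be split. P2rx3 overlaps Ssrp1 (303 TPM) on the opposite strand, so its reads cannot be told apart from those of Ssrp1 where strand is unknown.

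**Figure D2:**
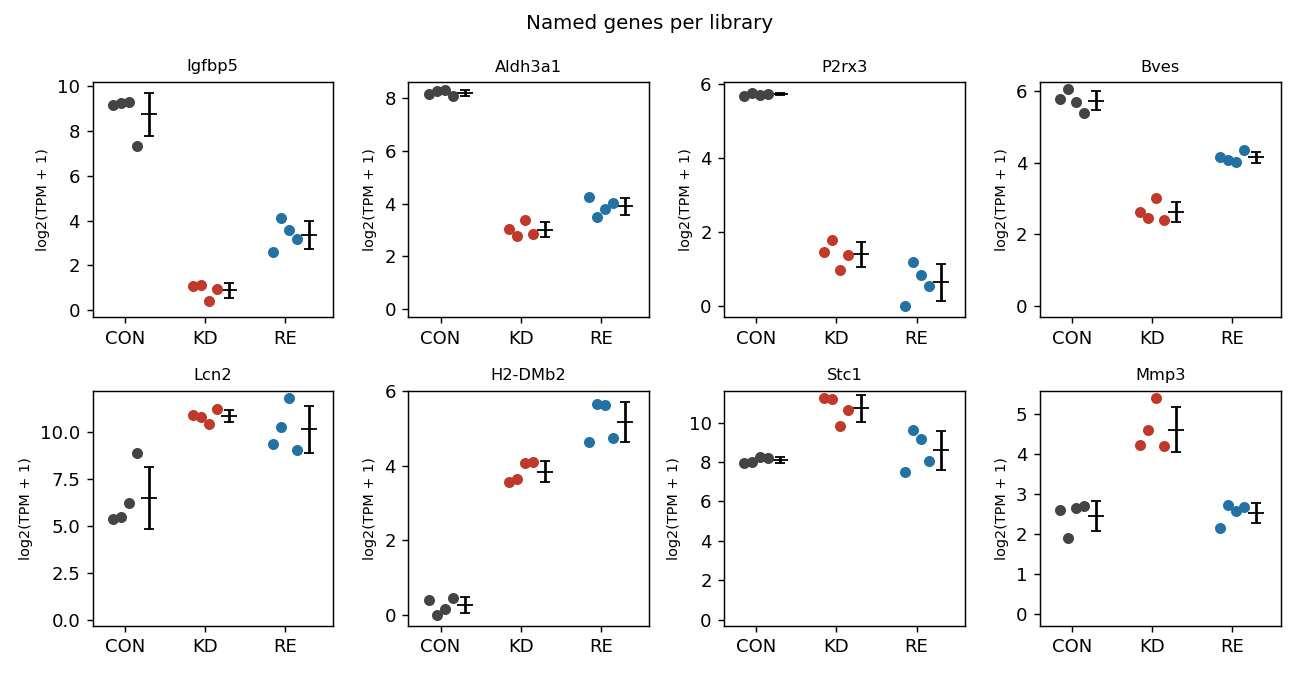
Expression of 8 genes as log2(TPM + 1) in CON, KD and RE, 1 point per library, with the group mean and SD as black bars. Igfbp5, Aldh3a1, P2rx3 and Bves are lower in KD than in CON, Lcn2, H2-DMb2, Stc1 and Mmp3 are higher, and Igfbp5 and Bves lie higher and Stc1 and Mmp3 lower in RE than in KD.

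The inflammation and interferon response lists were called higher in KD by camera, but not with an estimated correlation (adjusted p = 0.374 and 0.652). Of 23 tested inflammation and NF-kB targets, 10 rose and 0 fell in KD (10 and 0 adjusted over the list alone), and the list median was 0.72 (camera adjusted p = 1.32e-05, adjusted p = 0.374 with an estimated correlation). Beside Lcn2 they included Nos2 for inducible nitric oxide synthase (3.03 ± 0.31), the acute phase gene Saa3 (2.73 ± 0.50, from 2512 ± 1894 to 14010 ± 910 TPM) and the cytokine gene Il1a (2.38 ± 0.36). Of 35 tested interferon response genes, 8 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.000199, adjusted p = 0.652 with an estimated correlation). The antiviral gene Oas1a rose by 2.32 ± 0.42, the deubiquitinase gene Usp18 by 2.13 ± 0.51, the GTPase gene Igtp by 1.44 ± 0.32 and the signal transducer gene Stat2 by 1.43 ± 0.21. The interferon list counted 4 rises without CON 1, KD 1, KD 2 or KD 4 and 5 without CON 3. The call of Usp18 was lost without CON 1, KD 1, KD 2 or KD 4, with an adjusted p of up to 0.0666 without KD 4.

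Camera also called the glycolysis and cholesterol synthesis lists higher in KD, but not with an estimated correlation (adjusted p = 0.527 for both). Of 30 glycolysis and hypoxia genes, 7 rose and 1 fell (11 and 2 adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.000447, adjusted p = 0.527 with an estimated correlation). Adm for the vasodilator peptide adrenomedullin rose from 0, 0.252, 0 and 0.0846 TPM in the CON libraries to 5.04, 4.63, 0.966 and 3.86 TPM in the KD libraries. The collagen prolyl hydroxylase gene P4ha2 rose by 1.47 ± 0.17 and the glycolysis regulator Pfkfb3 by 1.27 ± 0.25, whereas Slc16a3 for the lactate exporter MCT4 fell by 2.06 on the log2 scale (SE 0.21). Of 24 cholesterol synthesis genes, 3 rose and 0 fell (13 and 0 adjusted over the list alone). The median was 0.58 (camera adjusted p = 1.23e-05, adjusted p = 0.527 with an estimated correlation). These were the sterol desaturase gene Sc5d (1.19 ± 0.29), Hmgcs1 for HMG-CoA synthase (1.13 ± 0.30) and Mvd for mevalonate decarboxylase (0.82 ± 0.23). Each of these 3 calls was lost in several fits that left out 1 library, with an adjusted p of up to 0.0762, 0.1004 and 0.138, each without KD 2. The cholesterol list counted 9 rises without CON 4 or RE 3, 1 without CON 2, KD 1 or KD 3, and 0 without CON 3, KD 2 or KD 4, and the glycolysis list 11 without CON 4. Fabp4, a fatty acid binding protein, and Lpl, lipoprotein lipase, rose by 3.23 ± 0.44 and 2.30 ± 0.25 in a fatty acid oxidation list of 21 genes that showed no shift (2 rose and 0 fell, 2 and 1 adjusted over the list alone, camera adjusted p = 0.743).

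The DNA replication and mitotic spindle lists were called lower in KD by camera, but not with an estimated correlation (adjusted p = 0.652 for both). Of 45 DNA replication and S phase genes, 0 rose and 7 fell over all genes tested, and 25 fell adjusted over the list alone. The median was -0.96 (camera adjusted p = 1.68e-10, adjusted p = 0.652 with an estimated correlation). The clamp loader genes Rfc3 and Rfc4 changed by -1.59 ± 0.38 and -1.01 ± 0.27, the replicative helicase gene Mcm7 by -1.18 ± 0.34 and the GINS complex gene Gins1 by -1.11 ± 0.28. Each of these 4 calls was lost in 5 to 7 of the 12 fits that left out 1 library, with an adjusted p of up to 0.0629 for Rfc3 without KD 2, 0.106 for Rfc4 without CON 1, 0.146 for Mcm7 without KD 2 and 0.0878 for Gins1 without KD 2. Mcm7 overlaps Cops6 (290 TPM) and Rfc4 overlaps Eif4a2 (232 TPM) on the opposite strand. Of 44 spindle assembly and mitotic kinase genes, 0 rose and 3 fell (0 and 2 adjusted over the list alone). The median was -0.57 (camera adjusted p = 9.43e-09, adjusted p = 0.652 with an estimated correlation). These were the kinetochore gene Spc24 (-1.21 ± 0.19), Birc5 for survivin of the chromosomal passenger complex (-0.86 ± 0.21) and the phosphatase gene Cdc25c (-0.72 ± 0.20). The calls of Birc5 and Cdc25c were lost without single libraries, with an adjusted p of up to 0.0772 without KD 2 and 0.119 without CON 2. Both lists depended on CON 4, in which long transcripts were low: without it 28 replication genes and 23 spindle genes fell, and without CON 4, RE 1 and RE 3 40 and 40 fell. Without RE 3 the counts were 21 and 10, the spindle count was 6 without KD 3 or RE 4, and both were 0 to 2 without CON 1, CON 2, CON 3, KD 1, KD 2 or KD 4.

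Among 41 centrosome and primary microcephaly proteins, the family to which Wdr62 belongs, 0 rose and 3 fell (0 and 3 adjusted over the list alone). The median was -0.24 (camera adjusted p = 0.0295, adjusted p = 0.966 with an estimated correlation). The augmin genes Haus8 and Haus1 changed by -0.91 ± 0.20 and -0.89 ± 0.15, and Tubg1 for gamma-tubulin by -0.66 ± 0.15. The list's call was lost without CON 1 (adjusted p = 0.157), CON 2 (0.0898) or KD 3 (0.102), and that of Tubg1 without CON 1, CON 3, KD 1 or KD 2 (up to 0.0626 without KD 2). Without CON 4, 10 of these genes fell, and without CON 4, RE 1 and RE 3 1 rose and 21 fell. Haus1 overlaps Atp5a1 (639 TPM) and Haus8 overlaps Myo9b (22.8 TPM) on the opposite strand. The replication-dependent histone mRNAs, which lack poly(A) tails, were listed as a sign of RNA quality. Being replication-dependent, they can also follow the share of dividing cells, so they cannot tell that from RNA quality. This list was called lower in KD along with the replication and spindle lists (adjusted p = 0.527 with an estimated correlation). Of its 23 genes 0 rose and 2 fell (0 and 5 adjusted over the list alone). The median was -0.63 (camera adjusted p = 0.000161, adjusted p = 0.527 with an estimated correlation). Hist1h1b changed by -1.25 ± 0.29 and Hist1h2bc by -1.03 ± 0.26. These 2 calls were lost without CON 1, CON 2, CON 3, KD 2 or KD 4, with an adjusted p of up to 0.0564 without CON 3 and 0.0788 without KD 4, and that of Hist1h2bc also without KD 1. The histone list counted 7 falls without CON 4 and 5 without KD 3 or RE 3. Among 16 G1 cyclins and cell cycle inhibitors 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.628). This was Ccnd1 for cyclin D1, at -1.11 ± 0.29, a call lost without any 1 of CON 1, CON 2, CON 3, KD 1, KD 2 and KD 4 (adjusted p of up to 0.0984 without CON 2). Without CON 4, 0 of the G1 genes rose and 4 fell.

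**Figure D3:**
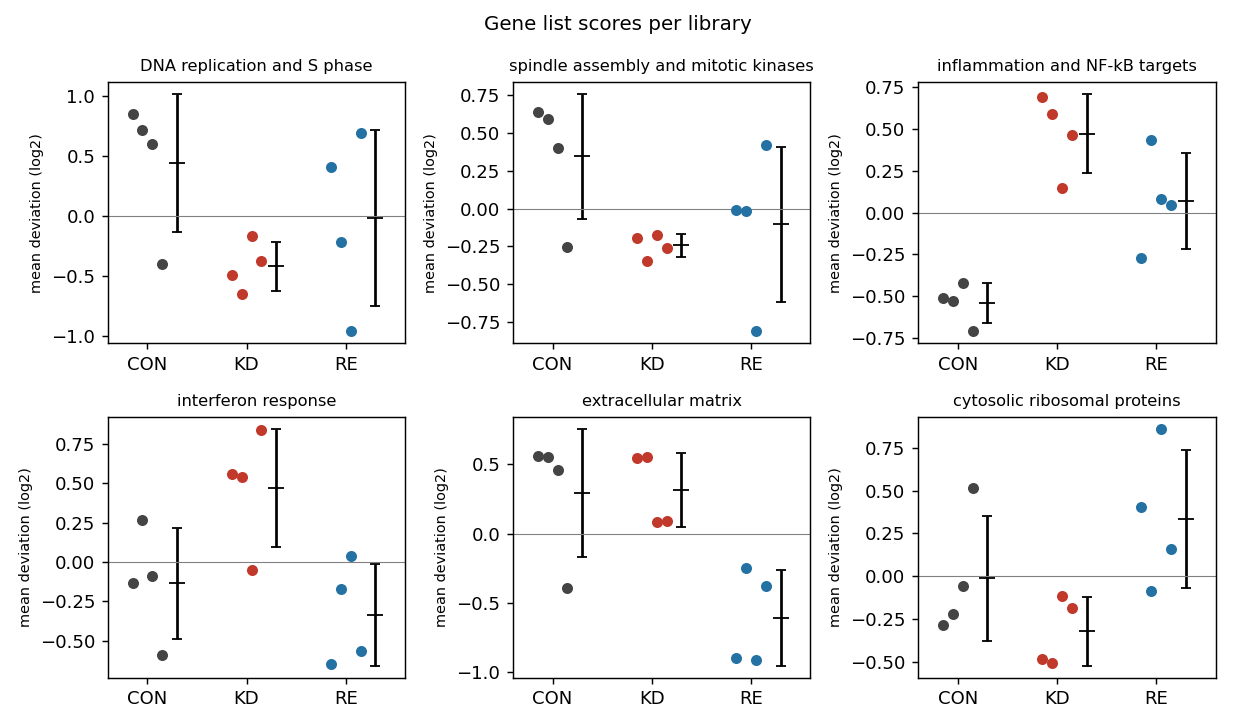
Mean deviation of the members of 6 gene lists from their gene means (log2 scale) in each library, 1 point per library, with the group mean and SD as black bars. DNA replication and spindle genes lie lower in KD than in CON on average, by -0.86 and -0.59, with overlap between the groups.

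Skeletal muscle markers were lower in KD as a list. Of 7 tested skeletal muscle markers, 0 rose and 5 fell in KD (0 and 5 adjusted over the list alone), with a median of -1.18 (camera adjusted p = 7.48e-06). In KD against CON no other list passed with an estimated correlation, as this one did (adjusted p = 0.0322). Myod1, the master regulator of skeletal muscle fate, was at 4.27 to 8.18 TPM in CON and listed at 0 in KD 1, KD 2 and KD 3. Skeletal alpha-actin, Acta1, changed by -1.66 ± 0.31, the acetylcholine receptor gene Chrna1 by -1.46 ± 0.20 and the myogenic factor gene Myf5 by -1.18 ± 0.32. The call of Myf5 was lost without any 1 of 7 libraries (adjusted p of up to 0.117 without CON 2). Of 9 tested sarcomere genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.879), Ldb3 for a Z-disc protein at 1.31 ± 0.25. Of 14 tested cardiac ion channel and calcium handling genes 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.948), Bves for a Popeye domain cAMP-binding membrane protein, at -3.10 ± 0.20. Of 16 cardiac transcription factors and inducers 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.628). They were Tbx18 (2.12 ± 0.34), Nkx2-5 (1.10 ± 0.27, lost without CON 1, CON 2, CON 3, KD 1 or KD 4, up to 0.0825 without KD 1) and Bmp4 (-0.72 ± 0.15). Of 12 cardiac stress genes 1 rose and 2 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.294), Hmox1 for haem oxygenase rising by 0.59 ± 0.15 and Acta1 and Atf3 falling. The call of Hmox1 was lost without CON 2, CON 3, KD 1, KD 3 or KD 4 (up to 0.0885 without KD 1), and that of Atf3 without CON 1 or CON 2 (up to 0.0526).

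In several other lists members changed in both directions with no net shift. Of 33 unfolded protein and integrated stress response genes, 12 rose and 8 fell (14 and 12 adjusted over the list alone; camera adjusted p = 0.863). The chaperone genes Sdf2l1 (2.40 ± 0.46) and Pdia4 (1.96 ± 0.26) rose, and Vldlr (-3.17 ± 0.20), a lipoprotein receptor gene, and Slc7a11 for the cystine transporter (-2.60 ± 0.31) fell. Without CON 4, 12 of these genes rose and 15 fell, 5 matrix genes rose and 8 fell, and 3 adhesion genes rose and 4 fell. Of 20 Wnt genes 5 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.734), among them the Wnt antagonist gene Sfrp1 at 3.10 ± 0.25 and the ligand genes Wnt4 at -3.15 ± 0.23 and Wnt7b at -2.63 ± 0.18. Of 41 extracellular matrix genes 5 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.755), with the collagen cross-linking genes Loxl2 (1.39 ± 0.29) and Loxl1 (1.39 ± 0.20) higher and the gelatinase gene Mmp2 (-3.18 ± 0.19) and Dcn for decorin (-2.65 ± 0.33) lower. Of 12 fibroblast markers 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.538), of 24 adhesion genes 3 rose and 2 fell (5 and 2; 0.742), of 28 TGF-beta and BMP genes 3 rose and 2 fell (3 and 3; 0.742), and of 12 Notch genes 1 rose and 2 fell (1 and 2; 0.834), in the same order of values. The adhesion gene L1cam (2.79 ± 0.31), the activin inhibitor gene Fst (2.25 ± 0.24), the glycosyltransferase gene Lfng (1.21 ± 0.17) and Mfap5 of elastic fibres (1.91 ± 0.40) rose, and the desmosomal gene Pkp1 (-2.08 ± 0.23) and the repressor gene Hes1 (-1.95 ± 0.29) fell.

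The oxidative stress, oxidative phosphorylation and ribosomal protein lists were called lower in KD by camera, and all 3 calls were lost without CON 4 and with an estimated correlation (adjusted p = 0.173, 0.652 and 0.792). Of 30 oxidative stress genes 4 rose and 5 fell (4 and 6 adjusted over the list alone). The median was -0.25 (camera adjusted p = 0.0143, adjusted p = 0.173 with an estimated correlation, 0.356 without CON 4). The glutathione transferase gene Gsta3 changed by -3.24 ± 0.21. Of 39 oxidative phosphorylation genes 0 rose and 2 fell (0 and 2 adjusted over the list alone). The median was -0.20 (camera adjusted p = 0.00662, adjusted p = 0.652 with an estimated correlation, 0.722 without CON 4, 0.0748 without KD 1 and 0.0996 with median-of-ratios scaling). Of 44 ribosomal protein genes 0 rose and 2 fell (0 and 0 adjusted over the list alone). The median was -0.30 (camera adjusted p = 0.000118, adjusted p = 0.792 with an estimated correlation, 0.561 without CON 4). The oxidative stress list counted 0 rises without CON 2, CON 3, KD 1 or KD 4 and 1 without CON 1 or KD 2, and the ribosomal list 6 falls without RE 3, 1 without CON 2 or KD 4 and 0 without CON 3, KD 1 or KD 2. The MAPK and JNK list (33 genes, 1 rise and 1 fall, 1 and 1 adjusted over the list alone, camera adjusted p = 0.834) held the Ras inhibitor gene Spry1 at -2.80 ± 0.34 and the phosphatase gene Dusp1 at 1.44 ± 0.23. Dusp1 overlaps Ergic1 (165.7 TPM) on the opposite strand. Immediate early genes (24 genes, 3 rises and 1 fall, 4 and 2 adjusted over the list alone, 0.834), p53 targets (29 genes, 2 and 0, 2 and 0 alone, 0.881), apoptosis regulators (27 genes, 0 and 0, 0 and 0 alone, 0.834), heat shock genes (20 genes, 2 and 1, 3 and 1 alone, 0.653) and smooth muscle markers (8 genes, 1 and 0, 1 and 0 alone, 0.0600) were not called by camera. Without CON 4, 2 MAPK and JNK genes rose and 3 fell, 8 immediate early genes rose and 3 fell, and 3 p53 targets rose and 4 fell. In that fit 1 apoptosis regulator rose and 2 fell, and 4 heat shock genes rose and 3 fell. The immediate early count was 0 or 1 rises without CON 1, CON 2, CON 3, KD 1, KD 2 or KD 4. The median, mean and camera direction differed in sign for G1 cyclins (0.01, -0.20, down), sarcomere genes (-0.17, 0.08, up), ion channels (0.28, -0.06, up), apoptosis regulators (0.01, -0.02, down) and fibroblast markers (0.08, -0.21, down). For immediate early and unfolded protein genes the mean lay just below 0 with a median of 0.17 and 0.11 and an upward direction.

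The size of the KD against CON result moved with single libraries. It was 2412 changed genes (1116 higher, 1296 lower) without CON 4, and 792 without CON 3, 765 without KD 1, 744 without KD 2 and 781 without KD 4. The 4 and 4 values did not overlap for 2230 genes (18.9%), where chance gives 2.86%.

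RE was compared with KD to find which genes moved when the WDR62 virus was added. The extracellular matrix list was lower in RE by camera (adjusted p = 0.509 with an estimated correlation), with Lama4 and Col12a1 among its falls, and Igfbp5 and the Popeye domain genes Bves and Popdc3 rose. The laminin gene Lama4 went from 51.2 ± 9.78 TPM in KD to 12.4 ± 2.81 in RE (-1.97 ± 0.21, adjusted p = 0.00263), and Aspn for the matrix proteoglycan asporin from 33.0 ± 8.19 to 7.74 ± 2.33 TPM (-1.97 ± 0.24, adjusted p = 0.00509). Bves rose from 5.24 ± 1.28 to 16.7 ± 1.89 TPM (1.52 ± 0.20, adjusted p = 0.00611). In total 123 genes changed, 22 higher and 101 lower, and 79 of them (11 higher, 68 lower) by at least 1 on the log2 scale.

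The median of all tested genes in RE against KD was itself -0.29, and after median-of-ratios scaling, which moved it to 0.00, 78 genes changed, 32 higher and 46 lower. Fold changes here are given as measured, and relative to that median each stands 0.29 higher. The other large falls were Col12a1 for a fibril-associated collagen (-2.39), Stc1 for the hormone stanniocalcin 1 (-2.14), the pattern recognition gene Ptx3 (-2.13), Mmp3 for stromelysin 1 (-2.09), the kinase gene Mark1 (-2.07) and Agt for angiotensinogen (-1.98), which are -2.10, -1.85, -1.84, -1.80, -1.78 and -1.68 relative to the median of all genes. Stc1 went from 1822 ± 726 to 451 ± 281 TPM and Mmp3 from 25.1 ± 11.3 to 4.85 ± 0.966 TPM. The other large rises were Igfbp5 (2.48, from 0.882 ± 0.392 to 10.1 ± 4.72 TPM), Glrx3 (1.47), H2-DMb2 (1.33), the imprinted noncoding RNA gene H19 (1.31), the histone variant gene H2afz (1.22), Popdc3 for a second Popeye domain protein (1.16) and Birc5 (1.08). The SE of these 16 changes ran from 0.20 for Bves and Popdc3 to 0.47 for Col12a1, and the adjusted p reached 0.0426 for H19. Of the 16 calls, 4 held in every fit that left out 1 library (Bves, Mmp3, Aspn and Lama4), and 2 of these, Aspn and Lama4, in every alternative run for single genes. The other 12 were lost in 5 to 9 of the 12 such fits, with highest adjusted p-values from 0.118 (Igfbp5, Glrx3 and Popdc3 without KD 2) to 0.175 (H19 without KD 1). Glrx3 and H2afz have processed pseudogenes that can take their reads, and Aspn overlaps Cenpp (41.0 TPM) on the opposite strand.

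Matrix genes made up the list with the most falls. Of 41 extracellular matrix genes 0 rose and 8 fell in RE against KD (0 and 30 adjusted over the list alone). The median was -0.93, or -0.64 relative to all genes (camera adjusted p = 2.37e-09, adjusted p = 0.509 with an estimated correlation). Beside Col12a1 and Lama4 they included Fn1 for fibronectin (-1.56 ± 0.33, from 1858 ± 616 to 619 ± 170 TPM) and the collagen gene Col1a1 (-1.05 ± 0.19). The calls of Fn1 and Col1a1 were lost in 9 and 8 of the 12 fits without 1 library (up to 0.193 and 0.150, both without KD 2). The list counted 32 falls without CON 4, 18 without RE 2, 13 without KD 3, 1 or 2 without any other library, and 4 without CON 4, RE 1 and RE 3. Across genes, which are not independent replicates, the fold changes of RE against KD fell with transcript length (Spearman rho -0.495), and with the length correction the matrix median was -0.35 and 6 genes fell (camera adjusted p = 1.68e-07). Of 12 fibroblast markers 0 rose and 2 fell (0 and 6 adjusted over the list alone). The median was -0.86 (camera adjusted p = 0.00828, adjusted p = 0.382 with an estimated correlation, 0.0526 without KD 3), and -0.46 with the length correction (0.00280). Col1a2 changed by -0.85 ± 0.17, a call lost in 9 of those fits (up to 0.172 without RE 1). Of 24 adhesion genes 0 rose and 1 fell (0 and 5 adjusted over the list alone). The median was -0.64 (camera adjusted p = 0.00186, adjusted p = 0.745 with an estimated correlation). The gene that fell was L1cam (-1.49 ± 0.31, up to 0.199 without KD 2). With the length correction the adhesion call was lost (adjusted p = 0.146). Of 28 TGF-beta and BMP genes 0 rose and 0 fell (0 and 1 adjusted over the list alone). The median was -0.65 (camera adjusted p = 0.0482, adjusted p = 0.776 with an estimated correlation), a call lost without KD 1 (0.0800), KD 3 (0.0814), RE 1 (0.0518), RE 2 (0.0508) or RE 3 (0.0925), and with the length correction (0.0808). Without CON 4, 7 fibroblast, 10 adhesion and 12 TGF-beta and BMP genes fell.

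The interferon response, cholesterol synthesis and stress response lists were called lower in RE than in KD by camera, with no single gene past the threshold, but not with an estimated correlation (adjusted p = 0.599, 0.733 and 0.745). Of 35 interferon genes 0 rose and 0 fell over all genes tested, and 15 fell adjusted over the list alone. The median was -0.86, or -0.57 relative to all genes (camera adjusted p = 0.000134, adjusted p = 0.599 with an estimated correlation). Stat2 stood at 52.6 ± 12.4 TPM in KD and 25.9 ± 4.56 in RE, and Oas1a at 15.8 ± 5.58 and 3.91 ± 2.49 TPM. Of 24 cholesterol synthesis genes 0 rose and 0 fell (0 and 8 adjusted over the list alone). The median was -0.50 (camera adjusted p = 0.0190, adjusted p = 0.733 with an estimated correlation, 0.0730 without KD 3 and 0.0504 without RE 2). Of 33 unfolded protein and integrated stress response genes 0 rose and 0 fell (0 and 5 adjusted over the list alone). The median was -0.40 (camera adjusted p = 0.0289, adjusted p = 0.745 with an estimated correlation, 0.0752 without KD 4, 0.203 without RE 4 and 0.0963 with median-of-ratios scaling). Without CON 4, 18 interferon, 9 cholesterol and 10 stress response genes fell. The interferon and stress response counts were 8 and 3 without KD 3 and 3 and 5 without RE 2.

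The ribosomal protein, oxidative phosphorylation, replication and spindle lists were called higher in RE than in KD by camera, but not with an estimated correlation (adjusted p = 0.310, 0.183, 0.565 and 0.599). Of 44 ribosomal protein genes 0 rose and 0 fell over all genes tested, and 22 rose adjusted over the list alone. The median was 0.53, or 0.82 relative to all genes (camera adjusted p = 8.12e-25, adjusted p = 0.310 with an estimated correlation). Of 39 oxidative phosphorylation genes 0 rose and 0 fell (5 and 0 adjusted over the list alone). The median was 0.30, or 0.59 relative to all genes (camera adjusted p = 2.08e-13, adjusted p = 0.183 with an estimated correlation). With the length correction the ribosomal median was 0.55 (camera adjusted p = 6.13e-11) and the oxidative phosphorylation median 0.35 (1.86e-06). Without CON 4, 25 ribosomal and 13 oxidative phosphorylation genes rose, and 3 and 4 rose without RE 2. The mean deviation of the ribosomal genes from their gene means was 0.86 in RE 3 and 0.41 in RE 1, which stood apart, -0.08 in RE 2 and 0.16 in RE 4, against -0.51 to -0.12 in the KD libraries. Of 45 DNA replication genes 1 rose and 0 fell (1 and 0 adjusted over the list alone). The median was 0.43, or 0.72 relative to all genes (camera adjusted p = 2.27e-12, adjusted p = 0.565 with an estimated correlation), and the gene that rose was Tk1 for thymidine kinase (0.98 ± 0.19). Of 44 spindle genes 1 rose, Birc5, and 0 fell (3 and 0 adjusted over the list alone). The median was 0.16, or 0.46 relative to all genes (camera adjusted p = 2.32e-07, adjusted p = 0.599 with an estimated correlation). The calls of Tk1 and Birc5 were each lost in 9 of the 12 fits without 1 library (up to 0.166 without KD 1), and without CON 4 each of these 2 lists counted 5 rises. With the length correction the replication and spindle medians were 0.71 and 0.50 (camera adjusted p = 6.13e-11 and 9.04e-11). The RE libraries did not move together. From RE 1 to RE 4 the mean deviation of the replication genes was 0.404, -0.217, -0.96 and 0.692, against -0.647 to -0.171 in KD. That of the spindle genes was -0.009, -0.013, -0.81 and 0.419, against -0.344 to -0.175 in KD. RE 3 thus lay below every KD library in both lists before the length correction. After it RE 3 lay within the KD range in both. It stood at -0.487 for replication genes (KD -0.808 to -0.14) and at -0.294 for spindle genes (KD -0.531 to -0.134). The histone mRNA list, replication-dependent but listed as a sign of RNA quality, was also called higher in RE than in KD (camera adjusted p = 0.000127, adjusted p = 0.459 with an estimated correlation).

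Of 30 oxidative stress genes 0 rose and 0 fell in RE against KD (7 and 0 adjusted over the list alone). The median was 0.13, or 0.42 relative to all genes (camera adjusted p = 3.48e-06), and this list also passed with an estimated correlation (adjusted p = 0.00979). Without CON 4, 8 of its genes rose, with 3 rises without KD 3 and 2 without RE 2. Of 23 histone mRNAs 0 rose and 0 fell (0 and 0 adjusted over the list alone). The median was 0.25 (camera adjusted p = 0.000127, adjusted p = 0.459 with an estimated correlation). Of 7 skeletal muscle markers 0 rose and 0 fell (1 and 0 adjusted over the list alone). The median was 0.18 (camera adjusted p = 0.0322, adjusted p = 0.325 with an estimated correlation, 0.108 without KD 3 and 0.0925 without RE 3). The histone call was lost with the length correction (adjusted p = 0.0808), and the skeletal muscle call with the length correction (0.0808) and with median-of-ratios scaling (0.0963). The other 17 lists were not called. Among their members Nkd2 of Wnt signalling (-1.57 ± 0.24), the immediate early gene Nr4a2 (-1.94 ± 0.38), the complement gene C3 (-1.57 ± 0.31) and Pfkfb3 (-1.33 ± 0.25) fell and the centrosome gene Haus1 (0.86 ± 0.15) rose. Each of these 5 calls was lost in 5 to 9 of the fits without 1 library, with an adjusted p of up to 0.0853 (Nkd2 without KD 2), 0.166 (Nr4a2 and C3 without KD 1), 0.157 (Pfkfb3 without KD 2) and 0.150 (Haus1 without KD 2). Medians below 0 stood beside an upward camera direction for G1 cyclins (-0.11), immediate early genes (-0.27), p53 targets (-0.33), glycolysis genes (-0.20) and fatty acid oxidation genes (-0.03). All but the p53 targets lay above the median of all genes, -0.29. Cardiac stress and heat shock genes had medians of 0.15 and 0.01 with means of -0.08 and -0.20.

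The number of genes changed in RE against KD moved by over 1.5 times with every single library left out. It was 36 without CON 1, 32 without CON 2, 27 without CON 3, 2791 without CON 4, 15 without KD 1, 13 without KD 2, 418 without KD 3, 22 without KD 4, 16 without RE 1, 517 without RE 2, 48 without RE 3 and 22 without RE 4. The CON libraries enter this count only through the spread that all groups share in the model. Without any 1 of them the median of all genes stayed at -0.292. The 4 and 4 values did not overlap for 1681 genes (14.3%, chance 2.86%).

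Genes that changed in KD against CON and changed in the opposite direction in RE against KD were counted as reversed. There were 78 such genes: 62 rose in KD and fell in RE, and 16 fell in KD and rose in RE. Stc1 stood at 273 ± 26.5 TPM in CON, 1822 ± 726 in KD and 451 ± 281 in RE, and Mark1 at 4.34 ± 0.215, 45.5 ± 16.3 and 11.4 ± 7.35 TPM. Serpina3m of the serine protease inhibitor family (1.01 ± 0.177, 14.2 ± 2.09 and 4.27 ± 0.717 TPM), the transporter gene Slc6a17, the adhesion gene L1cam and Slfn4 also rose in KD and fell in RE, by 2.91, 2.87, 2.79 and 2.61 and then -1.53, -1.22, -1.49 and -1.29 on the log2 scale. Igfbp5, H19 (79.4 ± 26.5, 3.15 ± 0.374 and 9.45 ± 2.48 TPM), Bves (52.6 ± 10.1, 5.24 ± 1.28 and 16.7 ± 1.89 TPM), Popdc3 (74.1 ± 14.7, 12.9 ± 1.21 and 30.6 ± 5.84 TPM), Ten1 of the telomere-capping CST complex and Glrx3 went the other way. Of the 78, 11 still differed from CON in the direction of KD. The RE against KD calls of 10 of these 12 named genes, those other than Bves and Serpina3m, were lost in 5 to 9 of the 12 fits without 1 library, with an adjusted p of up to 0.199 (L1cam and Slfn4 without KD 2). The KD against CON call of Glrx3 was lost in 5 of them (up to 0.0975 without KD 1). Reads counted for Ten1 may not all be its own, since the use of strand is unknown, and Serpina3m belongs to a cluster of near-identical genes.

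KD libraries enter both sides of the reversed count with opposite signs. Independent lists of these sizes would share 6.67 genes of the first kind and 0.79 of the second. In 100 simulations of unchanged groups with the shared KD libraries the median count was 0 and 1 simulation gave as many or more, with a maximum of 5430. These simulated groups hold no difference between KD and CON either. They therefore do not exclude chance or the shared KD libraries for the reversal. With 2 KD libraries in each comparison, so that none was shared, the count over 6 assignments was 3, 4, 1, 1, 0 and 69. In the same order RE against KD had only 5, 7, 2, 3, 1 and 376 changed genes in all. The low counts thus cannot tell a lack of reversal from a lack of calls. The 69 came with KD 3 and KD 4 in the comparison with CON, where 8 genes changed in the same direction in both. The correlation of the 2 fold changes across genes, which are not independent replicates, was -0.351 against a simulated -0.416, and their covariance -0.114 against a simulated -0.0427. The count was 22 without CON 1, 23 without CON 2, 20 without CON 3, 426 without CON 4, 9 without KD 1, 8 without KD 2, 261 without KD 3, 16 without KD 4, 13 without RE 1, 265 without RE 2, 34 without RE 3 and 15 without RE 4. With median-of-ratios scaling 47 genes were reversed, 27 of them higher in KD and 20 lower.

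RE was compared with CON to see what still differed after the virus was added. Several of the genes with the largest changes in KD still differed from CON in RE. Igfbp5 remained at 10.1 ± 4.72 TPM against 488 ± 221 in CON (-5.38 ± 0.44, adjusted p = 9.4e-06), Prl2c3 at 6.76 ± 7.93 against 228 ± 50.8 TPM (-5.88 ± 0.83), and P2rx3 was listed at 0 to 1.28 TPM against 50.4 to 53.1 TPM in CON. Cyp4f40 was listed at 0 in every RE library. The largest rises were H2-DMb2 (24.0 to 49.8 TPM in RE), H2-DMb1 (11.9 to 38.8 TPM), Camp (4.10 ± 0.36) and Hp (3.90 ± 0.51, at 2143 ± 1643 TPM), and these 8 calls held under every alternative run for single genes. In total 745 genes changed, 318 higher and 427 lower, and 524 of them (187 higher, 337 lower) by at least 1. The median of all genes was -0.27, and after median-of-ratios scaling, which moved it to 0.01, 1096 genes changed with 592 higher and 504 lower. Quantile normalization gave 672 higher and 506 lower.

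Of the 1202 genes changed in KD, 474 (39.4%) also differed from CON in the same direction in RE, 255 higher and 219 lower, and 1 in the opposite direction. Both comparisons use the CON libraries. Independent lists would share 20.99 higher and 15.41 lower genes. The median of 100 simulations of unchanged groups was 0, and 1 simulation gave as many or more (maximum 5430). These simulations also remove the KD against CON difference, so they do not test whether that difference is kept in RE. With 2 CON libraries in each comparison 223 to 322 genes changed in the same direction. The correlation of fold changes across genes was 0.645 against a simulated 0.508 and the covariance 0.257 against a simulated 0.0553, whose range of -0.0535 to 0.397 includes the observed value.

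Camera called the inflammation and glycolysis lists higher and the matrix list lower in RE than in CON, but not with an estimated correlation (adjusted p = 0.457, 0.457 and 0.951), and the matrix call was lost with the length correction (0.0647). Of 23 inflammation and NF-kB targets 5 rose and 0 fell (7 and 1 adjusted over the list alone). The median was 0.32, or 0.59 relative to all genes (camera adjusted p = 0.000106, adjusted p = 0.457 with an estimated correlation). Among them were Lcn2 (3.65 ± 0.73), Nos2 (2.84 ± 0.31) and Saa3 (2.48 ± 0.50). Of 30 glycolysis and hypoxia genes 7 rose and 2 fell (14 and 2 adjusted over the list alone). The median was 0.35 (camera adjusted p = 7.61e-05, adjusted p = 0.457 with an estimated correlation), with Ankrd37 at 2.005 ± 0.39 and Slc16a3 at -2.87 ± 0.21. Ankrd37 overlaps Ufsp2 (73.25 TPM) on the opposite strand. Without CON 4, 7 inflammation genes rose and 5 fell, and 14 glycolysis genes rose and 4 fell; 3 or 4 glycolysis genes rose without CON 1, CON 2, CON 3, RE 1, RE 2 or RE 4. Of 41 matrix genes 1 rose and 15 fell (1 and 19 adjusted over the list alone). The median was -0.74, or -0.47 relative to all genes (camera adjusted p = 6.35e-05, adjusted p = 0.951 with an estimated correlation). Mmp2 stood at -4.00 ± 0.19, Dcn at -3.18 ± 0.33, the protease inhibitor gene Timp3 at -2.75 ± 0.40 and the laminin gene Lama2 at -2.48 ± 0.43. Of the matrix genes 30 fell without CON 4 and 9 without any 1 of CON 1, CON 2, CON 3, RE 1 and RE 3. Of 12 fibroblast markers 1 rose and 6 fell (1 and 7 adjusted over the list alone). The median was -0.98 (camera adjusted p = 0.00694, adjusted p = 0.457 with an estimated correlation, 0.0631 without CON 4). Of 7 skeletal muscle markers 0 rose and 3 fell (0 and 4 adjusted over the list alone). The median was -0.67 (camera adjusted p = 0.00415, adjusted p = 0.328 with an estimated correlation, 0.0926 without CON 4). Without CON 4 the fibroblast and skeletal muscle medians were -1.28 and -0.96, against -0.41 for all genes.

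Camera also placed ribosomal protein genes (44 genes, 0 rises and 0 falls, 0 and 0 adjusted over the list alone, median 0.23, adjusted p = 3.62e-06, adjusted p = 0.898 with an estimated correlation) and oxidative phosphorylation genes (39 genes, 1 and 0, 0 and 0 alone, median 0.13, 0.00149, adjusted p = 0.745 with an estimated correlation) above other genes in RE against CON. Cholesterol genes were called higher (24 genes, 0 and 0, 0 and 0 alone, median 0.12, adjusted p = 0.0401, adjusted p = 0.971 with an estimated correlation), a call lost without CON 2 (0.0834), CON 3 (0.125), RE 1 (0.0783), RE 2 (0.0788) or RE 4 (0.176). With the length correction the calls of the oxidative phosphorylation (0.173), cholesterol (0.0574) and centrosome (0.0798) lists were lost. Centrosome genes were called lower (41 genes, 0 and 0, 0 and 0 alone, median -0.53, adjusted p = 0.0195, adjusted p = 0.999 with an estimated correlation), a call lost without CON 1 (0.0668) or RE 3 (0.0751). Without CON 4, 28 centrosome genes fell, 17 ribosomal genes rose, 10 oxidative phosphorylation genes rose and 2 fell, and 5 cholesterol genes rose and 2 fell. No DNA replication or spindle gene passed the threshold in RE against CON (0 and 0 of 45 and of 44 genes, 0 and 0 adjusted over the list alone by limma; medians -0.44 and -0.54, camera adjusted p = 0.463 and 0.249), and without CON 4 19 and 23 fell. Among lists not called, 8 of 33 unfolded protein and integrated stress response genes rose and 14 fell (10 and 16 adjusted over the list alone), among them Chac1 for a glutathione-degrading enzyme at -2.25 ± 0.40. Of 20 Wnt genes 3 rose and 6 fell (4 and 11 adjusted over the list alone), among them Sfrp2 at 2.40 ± 0.19 and Apcdd1 at -3.23 ± 0.36. Without CON 4, 10 Wnt genes fell, and the stress response list counted 3 or 4 rises without CON 1, CON 2, CON 3, RE 2 or RE 3. Medians below 0 stood beside an upward camera direction for interferon (-0.27), immediate early (-0.07), smooth muscle (-0.16), fatty acid oxidation (-0.09), oxidative stress (-0.05) and sarcomere genes (-0.01).

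The count of 745 was 433 without CON 1, 432 without CON 2, 417 without CON 3 and 6219 (1273 higher, 4946 lower) without CON 4. The 4 and 4 values did not overlap for 1085 genes (9.20%; chance 2.86%).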

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

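The tests of transcript length below were chosen only after the standing apart of CON 4, RE 1 and RE 3 had been seen. Within the groups of 4 libraries, 45 of 438 sets of values for named genes held 1 library whose gap to the nearest other library exceeded Dixon's 95% critical value, where chance gives about 1 in 20 sets. Of these, 22 were in CON 4 and 11 in KD 3. Gaps were taken on the log2(TPM + 1) scale, and values are given in TPM.

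In CON 4, 19 genes were lower than in the other CON libraries. Ptn was 16.3 (others 44.5 to 48.7), Igfbp5 158 (565 to 624), Fn1 984 (2300 to 2500), Lama2 3.06 (11.8 to 14.3), Itga6 13.1 (55 to 66.6) and Bmp5 2.46 (18.3 to 19). Cyp4f40 was 18.6 (28.6 to 30.6), Popdc3 52.2 (78.4 to 83.3), Rfc4 53.3 (101 to 114), Ccnd1 98 (207 to 239), Ldb3 4.81 (8.2 to 8.49), Sesn1 34.5 (60.9 to 68.3) and Vldlr 5.23 (10.2 to 10.5). Apcdd1 was 5.76 (20 to 22.7), Chrna1 8.27 (13 to 14.1), Hist1h1b 1.43 (4.63 to 4.99), Spry2 13.3 (21.1 to 22.5), Klf4 23.4 (101 to 127) and Sesn2 14.7 (62.8 to 76.2). Mvd at 46.4 (23.9 to 26.3), Gstm2 at 72.7 (31.5 to 34.9) and Rps9 at 4650 (3990 to 4020) were higher there.

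In KD 3, Pex5l was 15.2 (others 24.3 to 25), Prl2c2 6.2 (17.7 to 21.2), Ptx3 35 (76.9 to 88.9), Slfn4 6.51 (11.3 to 12.6), Fas 88.3 (94.1 to 95.1), Stat2 34.3 (55.9 to 61.8), Gstm2 77 (89.5 to 92.3) and Loxl1 106 (120 to 123). H2-DMb1 at 16 (9.51 to 10.2), Cdc25c at 23.8 (18.9 to 19.4) and Bnip3 at 291 (145 to 156) were higher. In KD 4, Igfbp2 was 0.189 and Myod1 0.125, both listed at 0 in the other KD libraries, and Col1a1 was 41.8 (61.8 to 64.4). In RE 2, Atf3 was 5.59 (2.7 to 2.85), Chac1 98.4 (34.7 to 37.9) and Wnt4 0.129 (0.446 to 0.514). In RE 3, Mfap5 was 192 (107 to 115), Myod1 0.133 (listed at 0 in the others) and Spry2 7.32 (9.74 to 10.3). Single values were Mmp3 in CON 2 at 2.72 (5.04 to 5.53), Hist1h1b in KD 1 at 1.89 (0.693 to 0.775) and Fosl1 in KD 2 at 104 (143 to 148).

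CON 4, RE 1 and RE 3 lay together at the low end of the first principal component, which held 61.8% of the variance. Neither a single scaling factor per library nor a trend on transcript length accounts for all of this: the component still held 55% after median-of-ratios scaling and 47.5% after the length correction (42% to 52.6% with any library left out), with CON 4, RE 1 and RE 3 still lowest on it at -0.251, -0.26 and -0.521 against -0.162 for the next, KD 3. The gene loadings rose with transcript length across genes, which are not independent replicates (Spearman rho 0.545), and fell with GC content at a given length (partial rho -0.324). A trend on length, as RNA quality or library preparation may give, stays open as a part of it, and a trend on GC content as a candidate explanation, and the labels name no batch with which to part them. No biological explanation was tested, as no group of the design holds these 3 libraries.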

How the results depend on the processing

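The length correction, the array weights, the fits without CON 4, RE 1 and RE 3, the fits without CON 4 but with the length correction, the block with the length correction and the list tests without each library were chosen after seeing the data. No call of a named gene or a list changed direction past the threshold, but the balance of rises and falls did. Of the genes changed in KD against CON, 64.6% were higher. This was 46.3% without CON 4, 40.6% with array weights and 36.2% without CON 4, RE 1 and RE 3. It was 55% to 68.5% otherwise. In RE against CON 42.7% were higher. Median-of-ratios scaling gave 54%, quantile normalization 57%, the length correction 58.8%, and that correction without CON 4 52.7%. The other settings gave 20.5% to 47.3%. Of 4020 results for single named genes under an alternative, 3387 kept their call, 633 lost it and 0 reversed. Wdr62 in KD against CON stayed between -2.25 and -1.56; in RE against KD, where it was not called, it lay between -0.10 and 0.60. With a filter of 5 TPM Wdr62 has no value, since it is not tested.

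Requiring a log2 fold change of at least 1 left 693 genes in KD against CON and 79 in RE against KD, by construction. A filter of 5 TPM gave 452 genes in RE against CON, and fits of the 2 compared groups alone gave 49 in RE against KD, 409 in RE against CON and 29 reversed genes; both use fewer genes or libraries. For the other settings the cause was not tested. Median-of-ratios scaling gave 78 genes in RE against KD and 47 reversed genes. Quantile normalization gave 1904 in KD against CON and 1178 in RE against CON, and the length correction 2206 and 1367. Array weights, which set CON 4 to 0.09 and RE 3 to 0.166, gave 6433 in KD against CON, 5305 in RE against KD, 6386 in RE against CON and 2156 reversed. Without CON 4, RE 1 and RE 3 the counts were 4636, 50, 3781 and 37, and without CON 4 but with the length correction 3644, 1629, 5112 and 493, in the same order. Leaving out 1 library gave 744 (KD 2) to 2412 (CON 4) genes in KD against CON, 13 (KD 2) to 2791 (CON 4) in RE against KD, 417 (CON 3) to 6219 (CON 4) in RE against CON and 8 (KD 2) to 426 (CON 4) reversed. Of 93 list tests 35 passed, and 2 passed with an estimated correlation. By fry, which asks another question, 23 passed. They hold 16 of the 35 camera calls, and 19 of those calls did not pass. Of the camera calls in KD against CON, fry passed skeletal muscle (adjusted p = 4.79e-06), oxidative stress (0.000118), inflammation (0.00807), glycolysis (0.0174) and cholesterol (0.0305). The others had a fry adjusted p of at least 0.0553, among them interferon, replication and spindle (0.122 each). Leaving out 1 library gave 30 to 37 list calls, and the other alternatives run on all 93 tests 26 to 32.

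With the replicate number as a block, 15 genes changed in RE against KD and 12 were reversed, and with the block and the length correction 18 and 15. All 14 list calls of RE against KD, the only comparison fitted with the block, held under it. Same-numbered KD and RE libraries deviated from their group means with correlations of -0.554, 0.652, 0.239 and -0.252, so the numbers were not shown to pair the libraries. Pairing is not excluded, as larger differences between single libraries could hide it. Not every library correlated best with its own number: KD 1 and KD 2 did so with RE 2, and KD 3 and KD 4 with RE 1. No paired analysis was possible because the control columns carry no replicate number from the labels, for KD against CON and RE against CON. The table holds no depth, so what depth limits is unknown.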

Other observations

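Tests chosen only after the result was seen are those of shared CON libraries, chromosome copy number and Wdr62 level for the changes kept in RE, and all those of the DNA replication and spindle lists. The cardiac actin gene Actc1, the myosin light chain genes Myl7 and Myl2, the calcium pump regulator Sln and the Z-disc gene Actn2 were listed at 0 in all 12 libraries, and the myosin heavy chain gene Myh6 reached at most 0.209 TPM. Of 35 sarcomere genes 9 were tested and 24 stayed below 1 TPM in every library, as did 23 of 39 cardiac ion channel and calcium handling genes. The label of a cardiac muscle line thus had little listed expression of sarcomere genes behind it, and the cardiac list results rest on the few members tested. Desmin (Des) stood at 420 ± 144, 325 ± 42.9 and 400 ± 99.8 TPM in CON, KD and RE, the gap junction gene Gja1 at 670 ± 93.1, 819 ± 102 and 552 ± 153 TPM, cardiac troponin T (Tnnt2) at 20.7 ± 6.61, 15.7 ± 2.17 and 20.2 ± 4.27 TPM, and the collagen gene Col3a1 at 2955 ± 565, 2913 ± 532 and 1612 ± 455 TPM. Marker lists of other cell types with fewer than 5 members at a mean of at least 1 TPM were not tested: endothelial (4 of 17), immune (4 of 15), epicardial and epithelial (3 of 14) and neuronal (3 of 20). Of these, named after their values were seen, mesothelin (Msln) fell from 110 ± 9.26 TPM in CON to 28.1 ± 3.24 in KD (limma adjusted p = 1.51e-06) and stood at 25.7 ± 0.751 in RE, and keratin 19 (Krt19) fell from 26.5 ± 7.89 to 1.29 ± 0.669 TPM (limma adjusted p = 5.95e-06) and stood at 0.794 ± 0.524.

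At least 5 TPM in every CON and below 1 TPM in every KD library were 16 genes, and all 16 were below 1 TPM in every RE library too. Among them were Ces2g, Chrnd, Cldn34b1, Cyp4f40, Foxa2, Igfbp2, Kctd15, Mal, Parm1, Scara5, Slc7a3, Sprr2h, Sulf1, Vldlr and Wnt4, chosen after their values were seen. Mal and Parm1 were listed at 0 in all KD and RE libraries. The other way round were 5 genes, Adgrg3, H2-DMb1, H2-DMb2, Nrap and Pik3c2b, of which 2, H2-DMb1 and H2-DMb2, were at least 5 TPM in every RE library. After the length correction, whole chromosomes were shifted a little: the medians of chromosomes 6 and 19 were 0.20 and 0.19 in KD against CON and 0.22 and 0.28 in RE against CON, and that of chromosome 15 was -0.12 and -0.13. Those of chromosomes 13, 10 and 16 were 0.161, 0.125 and 0.12 in KD against CON and 0.049, 0.101 and 0.091 in RE against CON.

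Of the 1202 genes changed in KD, 474 differed from CON in the same direction in RE. Use of the same CON libraries alone does not give this: with 2 CON libraries in each comparison at least 223 genes changed in the same direction and at most 3 in opposite directions. A deviation common to all CON libraries would stay in both comparisons, so it is not excluded. An earlier test of shared CON libraries, whether the covariance of 0.257 lay outside the simulated range of -0.0535 to 0.397, had not excluded them. The bound on chromosome medians was also rewritten after the values were seen. After the length correction 912 genes were shared, so a length trend does not account for most of this overlap. Of the 474 genes, 470 had a position, and 77.7% of these lay outside chromosomes shifted by 0.1 in their direction. Whole-chromosome copy number thus does not account for most of them, but copy changes of parts of chromosomes were not tested. That Wdr62 was not restored in RE may be an explanation (log2 fold change 0.05 against KD), but it cannot be told apart from a lasting difference between the cells, such as one from the selection of edited cells, since the construct may not be counted.

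The DNA replication and spindle lists were lower in KD than in CON and higher in RE than in KD by camera, calls that were lost with an estimated correlation (adjusted p = 0.652 for both lists in KD against CON, 0.565 and 0.599 in RE against KD). In KD against CON a length trend does not account for this, as the smaller ratio of the list differences after and before the length correction was 1.002 and the 4 and 4 libraries then did not overlap (exact two-sided permutation p = 0.0286, against 0.0857 before). In RE against KD the ratio was 1.658 and the trend held -0.26 ± 0.13 and -0.30 ± 0.14 (SE) of differences of 0.40 and 0.14, a bound written after these values were seen, so a length trend does not account for this either, though the differences did not pass the exact test before (p = 0.371 and 0.629) or after the correction (0.143 and 0.0571). With 2 KD libraries in each comparison the differences kept opposite signs in all 6 assignments, with at least 0.572 of their size; by the bound first written this excluded the shared KD libraries, but the bound did not ask that the RE difference itself pass, so this stays open. A lower share of dividing cells in KD, a difference in RNA quality, and a response to the pCDH vector that the labels state for CON and RE only may also be behind the pattern. These were not tested. The histone mRNA list moved the same ways, but being replication-dependent it does not tell dividing cells from RNA quality.

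For the KD against CON count only the real split of the 8 libraries gave 1202 genes, 1 of 35 splits, and the highest other gave 0. The same holds for RE against KD (1 of 35 splits, 123 genes, highest other 0). A share of 1 in 35 is the least these splits can give, and the libraries may not be separate cultures. The splits therefore speak against chance for these libraries only. The RE against KD count also moved between 13 genes (without KD 2) and 2791 (without CON 4, which bears on it only through the shared spread). For the reversed genes 1 of 100 drawn splits of the 12 libraries gave 78, the real one, and the highest other gave 1, but these splits also undo the KD against CON difference, so they do not exclude chance for the reversal or the shared KD libraries. For RE against CON chance is not excluded: 3 of 35 splits gave at least 745 genes. The highest other gave 6847, with CON 4 exchanged for RE 4, which points to a structure of the libraries, CON 4 lying with RE 1 and RE 3. Loss of the chromosome segment around Wdr62 does not account for its fall, as the 38 other tested genes within 500 kb had a median log2 fold change of -0.003 in KD against CON.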
